A study of Homo sapiens with 8 samples.

How the data were processed

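Per the labels, chromatin of MCF-7 cells below passage 20 was precipitated with an antibody against BAF155, and per the labels' protocols barcoded libraries of 400 to 500 bp fragments were amplified by 4 and then 14 cycles of PCR and sequenced as 50 nt single reads, 12 libraries to a lane. Per the submitters' processing notes, Bowtie and HOMER were used and the genome builds mm9 and hg19 were named, without versions of the tools. All chromosome names and ends of the peaks fit hg19 and the mouse build has fewer chromosomes, so hg19 was used. Per the file headers, the authors called peaks separately in each ChIP library with HOMER's findPeaks in region mode, with a peak size of 1000 bp, a minimum distance of 2500 bp, at most 1 tag considered per bp, a false discovery rate of 0.001, a minimum of 4 times the local density and no control library in the command. Neighbouring peaks were stitched into regions of variable width, and replicates were not pooled. The deposited score of each peak, per the file headers and the sums of the files, is HOMER's normalised tag count per 10000000 total tags, rounded to whole numbers, not a raw count. It includes duplicate tags, whereas the peak threshold was set on non-duplicate tags.

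The files hold peak lists only, so depth was taken from their headers: 16979782, 18829317, 13429550 and 11229821 total tags in wild type replicates 1 and 2 and mutant replicates 1 and 2. Tags left after at most 1 per bp were 53.0%, 26.8%, 55.9% and 34.8% of these. The peak threshold was 18, 14, 17 and 13 tags, which is 4.00, 5.55, 4.53 and 6.66 times the density expected from non-duplicate tags spread over the genome. A library with fewer non-duplicate tags thus needed a stronger enrichment for a peak. Shares of peaks in a library carry exact Clopper-Pearson 95% intervals.

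The comparisons, their tests, 10 gene lists, 7 sequence motifs and the rule for named genes were fixed before the data were examined. Peaks of different libraries that overlapped by at least 1 bp were merged into regions. A region was called wild-type-only when both wild-type libraries and no mutant library had a peak in it, mutant-only in the reverse case, and shared when all 4 libraries had one. The same counts were made for the other partings of the 4 libraries into 2 and 2. Overlap was set against 1000 seeded random placements of the peaks on their own chromosomes and, as an alternative, within 500 kb either way. A peak was at a promoter when its centre lay within 1 kb of a start site of one of 20136 protein-coding genes of GENCODE version 44 lifted to GRCh37, and otherwise exonic, intronic or intergenic. Mitochondrial peaks were left out of annotation, motifs and placement, since the reference holds another mitochondrial sequence. The input libraries came without files, so signal was not divided by input.

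Gene lists covered MYC and its targets, oestrogen-responsive genes, luminal epithelial identity genes, basal and mesenchymal markers, SWI/SNF subunits, protein arginine methyltransferases, ribosomal protein genes, cell cycle genes, immediate early and stress genes, and haematopoietic and stromal markers for cell types not in the line. All members but PECAM1 were annotated. A gene was near a region when a start site lay within 50 kb. Lists were compared between wild-type-only and mutant-only genes by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over lists and a threshold of 0.05, against the genes near any region; genes near both classes were left out. Odds ratios given with Fisher's tests, and their intervals, had a small constant added to each count, so they stay finite where no member is counted. The comparison of lists with all protein-coding genes was added later. Motifs were matched on both strands against stretches of equal width 10 kb away, which not every region had. Named genes were members of the lists with a region called in both libraries of a genotype within 50 kb of a start site, the genes nearest to the 10 highest-scoring regions of each class (ranked by the worse rank among the libraries that call them), and SMARCC1 and CARM1. Of these, the text gives examples for each list.

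Group means were compared by exact permutation tests, two-sided, on 2 libraries against 2. Alternatives were a reciprocal overlap of 50%, centres within 500 bp, equal list lengths, peaks within 1000 bp merged, removal of chromosomes 1, 3, 17 and 20, other distances to start sites, each replicate left out, and the replicate number as a block. Later alternatives were a common limit on tag density, unstitched peaks, bins of 2% GC content (Mantel-Haenszel odds ratio) and regions away from promoters.

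Overlap, gene lists, motifs and the promoter share within GC bins were tested on simulated data; counts of regions, peak numbers, thinning and chromosome shares were not. For overlap, 100% of planted overlaps were found, and 3624 peaks placed at random had a mean fold of 0.986. For lists near any region of the 20136 genes, lists whose members were drawn with weight 4 were called in 99.5% of draws, with a false call in 7% of draws. For wild-type-only against mutant-only genes, 997 in all, a list of 20 genes drawn with weight 8 among the mutant-only genes was called in 33% of draws and with weight 16 in 81%. For motifs, 100% of planted matches were found. For the promoter share within GC bins, 1 list had 3600 peaks and the other more. An odds ratio made with 1 came back as 1.02, and as 2.60 without bins, and one made with 2 came back as 2.00. The 95% intervals held the made value in 98% and 90% of draws. The smaller numbers of wild-type-only and mutant-only regions were not simulated. Computation used python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, pysam 0.24.0, bedtools 2.31.1 and matplotlib 3.10.9.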

Results

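BAF155, the protein coded by SMARCC1 and a core subunit of the SWI/SNF chromatin remodelling complexes, was mapped by ChIP-seq in MCF-7 cells, a breast cancer line that expresses the oestrogen receptor. The design concerned methylation of BAF155 at residue R1064, and the question was whether BAF155 sits at other places on chromatin in mutant than in wild-type cells. The series held 8 samples in 4 groups of 2: BAF155 ChIP from wild-type cells, BAF155 ChIP from mutant cells, and an input library beside each ChIP. The 4 input libraries had no peak list and were not analysed here. The labels of the mutant samples conflicted, since their titles name a BAF155 mutant and their genotype field names a CARM1 knockout. CARM1 is an arginine methyltransferase. They are called mutant libraries throughout, and the peak lists cannot tell which label is right. Total sequenced tags were 16979782 and 18829317 in wild type replicates 1 and 2, and 13429550 and 11229821 in mutant replicates 1 and 2. After at most 1 tag per bp, 9002000, 5044000, 7502000 and 3906000 tags remained in the same order. The score of each peak was the authors' own value, a normalised tag count per 10000000 total tags, and it is called normalised tags. Values given in fours follow the order wild type 1, wild type 2, mutant 1 and mutant 2. Coordinates are hg19.

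BAF155 peaks were called at FOXA1, GRHL2, MYC, CLDN4 and PRMT6 in all 4 libraries. Regions shared by all 4 lay within 50 kb of 11 of 24 luminal epithelial identity genes and of 2 of 30 genes of the MYC list. The region over FOXA1, which codes for a pioneer factor of luminal breast cells, spanned chromosome 14, 38055662 to 38067002, with peaks of 252, 180, 206 and 130 normalised tags. GRHL2, an epithelial transcription factor gene, lay under a region of chromosome 8, 102492918 to 102553435, with peaks of 1028, 361, 486 and 488 normalised tags. The promoter of MYC, a growth-driving transcription factor gene, lay under a region of chromosome 8, 128745354 to 128752547, with 127, 91, 85 and 74 normalised tags. CLDN4, which codes for a tight junction protein, lay under a promoter region of chromosome 7, 73240657 to 73248590, with 168, 121, 174 and 214 normalised tags. PRMT6, an arginine methyltransferase gene, lay under a promoter region of chromosome 1, 107593976 to 107603263, with 250, 208, 212 and 137 normalised tags. The GRHL2 region was 60518 bp wide, and chromosome 1 is among the chromosomes on which tags were concentrated, as given below. Signal was not divided by input, so a part of DNA copy number in these tags was not tested.

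Overlap between the 4 peak lists was far above chance. Of the peaks in the shorter list, 61.1% overlapped a peak of the other list between the wild-type libraries and 56.9% between the mutant libraries. Across genotypes the same share was 55.8% for the replicate 1 libraries and 46.1% for the replicate 2 libraries. It was 65.2% between wild type 1 and mutant 2 and 47.6% between wild type 2 and mutant 1. The same peaks placed at random on their chromosomes gave shares lower by 22.5-fold to 27.6-fold, and p was 0.001 for every pair of libraries, the smallest that 1000 placements can give. Against random placement within 500 kb either way, which keeps local peak density, the excess was 3.05-fold to 3.42-fold, also with p of 0.001. The mean Jaccard index in bp was 0.368 within genotypes and 0.38 between them, a difference of -0.0122 with a two-sided exact permutation p of 1. With 2 libraries against 2, the smallest p that this permutation test can give is 0.33, so no comparison of group means by it could pass 0.05. The labels do not say that replicates came from separate cultures, so the spread between them may be technical only.

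Luminal epithelial identity genes were the list most often near BAF155: 21 of 24 had a region within 50 kb of a start site, against 35.3% of the 20136 protein-coding genes. The odds ratio was 11.3 (95% interval 3.64 to 34.9), and the two-sided Fisher's exact test gave a Benjamini-Hochberg adjusted p of 1.86e-06 over 10 lists. Over the other settings the odds ratio ranged from 7.80, without replicate 2, to 21.6, without chromosomes 1, 3, 17 and 20. The test takes genes as independent and equally likely to be near a region. Neighbours such as KRT8 and KRT18 can share a peak, and genes with widely spread start sites have more chances. The simulated lists allowed for neither. Immediate early and stress genes followed, with 18 of 22 near a region (odds ratio 7.55, 2.69 to 21.2, adjusted p 5.19e-05). Of these genes, 17, 9, 10 and 8 were near a peak in the 4 libraries, and without replicate 1 the odds ratio was 4.41 (adjusted p 0.00213). FOS, a subunit gene of AP-1, had peaks within 50 kb in all 4 libraries, of 22, 95, 19 and 22 normalised tags, and MCL1, a survival gene, had peaks of 80, 30, 30 and 55. Oestrogen-responsive genes were near a region in 20 of 30 cases (odds ratio 3.58, 1.70 to 7.55, adjusted p 0.00257). XBP1, a secretory stress factor gene, had closest peaks of 182, 41, 37 and 17 normalised tags, and CCND1, the cyclin D1 gene, had 46, 37, 20 and 39.

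**Figure D1:**
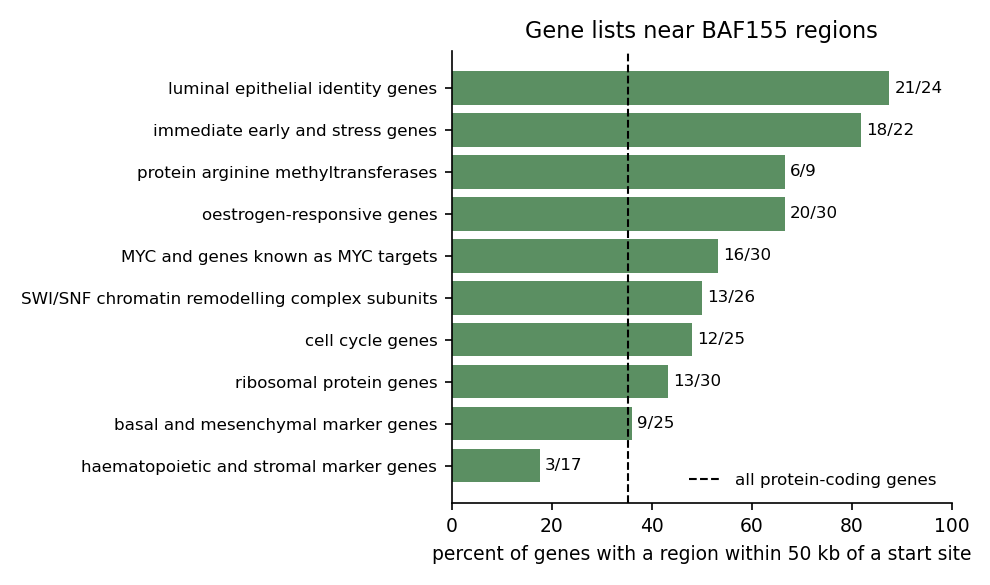
Percent of the genes of each of 10 lists with a BAF155 region of any library within 50 kb of a start site; numbers at the bars are genes near a region over genes annotated, and the dashed line marks all protein-coding genes. Luminal identity genes stand highest at 21 of 24 and haematopoietic and stromal markers lowest at 3 of 17, against 35.3% for all genes.

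MYC and its known targets had 16 of 30 genes near a region (odds ratio 2.09, 1.03 to 4.23, adjusted p 0.135), which did not pass, but the adjusted p was 0.0156 without replicate 1. This list was drawn up with knowledge of the study's interest in MYC targets, so it is not independent evidence. Protein arginine methyltransferases had 6 of 9 (adjusted p 0.151) and SWI/SNF subunits 13 of 26 (adjusted p 0.249). Cell cycle genes had 12 of 25 (adjusted p 0.263), ribosomal protein genes 13 of 30 (adjusted p 0.386) and basal and mesenchymal markers 9 of 25 (adjusted p 1). Haematopoietic and stromal markers, which stand for cell types absent from the line, had 3 of 17 (adjusted p 0.263). SMARCC1 itself had no peak closer than 5480338 bp in any library. CARM1 had a peak of 27 normalised tags at 32407 bp in wild type 2 and of 19 at 32356 bp in mutant 1, and none within 50 kb in the other libraries. This comparison with all genes was chosen after the data had been seen.

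Wild-type libraries held more BAF155 peaks: 10987 and 5225, against 6733 and 3625 in the mutant libraries. Genes with a peak within 1 kb of a start site numbered 2193 and 1077 in wild type and 1488 and 1009 in mutant libraries. The mean was 8106 ± 4074 peaks in wild type and 5179 ± 2198 in mutant (SD, n = 2 each), a ratio of 1.57 with a two-sided exact permutation p of 0.667. The difference of 2927 peaks was smaller than the spread between the wild-type replicates. Within the replicate numbers the ratio was 1.63 and 1.44, where the wild-type library also held 1.2 and 1.29 times the non-duplicate tags. Per 1000000 non-duplicate tags the libraries held 1221, 1036, 897 and 928 peaks, a ratio of means of 1.24 (exact permutation p 0.33). The peak threshold, set on non-duplicate tags, stood for 20.0, 27.8, 22.7 and 33.3 normalised tags per kb at the average duplication of each library, and peaks were reported on both sides of these densities. With peaks under 33.3 per kb left out in all 4 libraries, a common limit which kept 1.32%, 24.4%, 3.43% and 47.3% of the peaks, the ratio turned to 0.729.

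**Figure D2:**
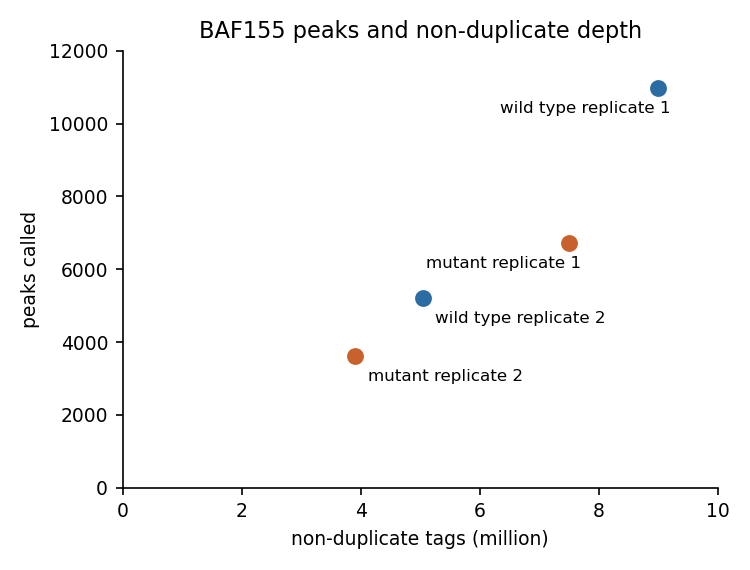
Peaks called in each BAF155 library (vertical axis, number of peaks) against tags left after at most 1 tag per bp (horizontal axis, tags divided by 1000000), with 1 point per library, blue for wild type and orange for mutant. Libraries with 9002000 and 7502000 tags have 10987 and 6733 peaks, and those with 5044000 and 3906000 have 5225 and 3625.

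Peaks of both wild-type libraries and neither mutant library stood at 753 regions, and the reverse held at 177 regions. DDX18, an RNA helicase gene known as a MYC target, had a wild-type-only region at its promoter on chromosome 2, 118571232 to 118572761, with 19 and 30 normalised tags. Its nearest mutant peaks lay 263303 and 2189889 bp away. GADD45A, a growth arrest gene, had a wild-type-only region on chromosome 1, 68152283 to 68153849, with 23 and 30 normalised tags, and no mutant peak closer than 6041492 bp. With lists of equal length, DDX18 and GADD45A each had a peak in 1 wild-type library, so neither was wild-type-only there. PRMT2, an arginine methyltransferase gene, had 22 and 36 normalised tags at its promoter on chromosome 21, 48055292 to 48056806, and BUB1, a spindle checkpoint kinase gene, had 19 and 20 on chromosome 2, 111435437 to 111437049. The reverse was seen at the promoter of TFF1, a classic oestrogen target: mutant peaks of 44 and 38 normalised tags on chromosome 21, 43785771 to 43787715. The closest wild-type peaks to TFF1 lay 14581 bp and 127340 bp away. At the common limit on tag density, 0 wild-type libraries had a peak within 50 kb of DDX18 or GADD45A, and 0 mutant libraries had one near TFF1.

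**Figure D3:**
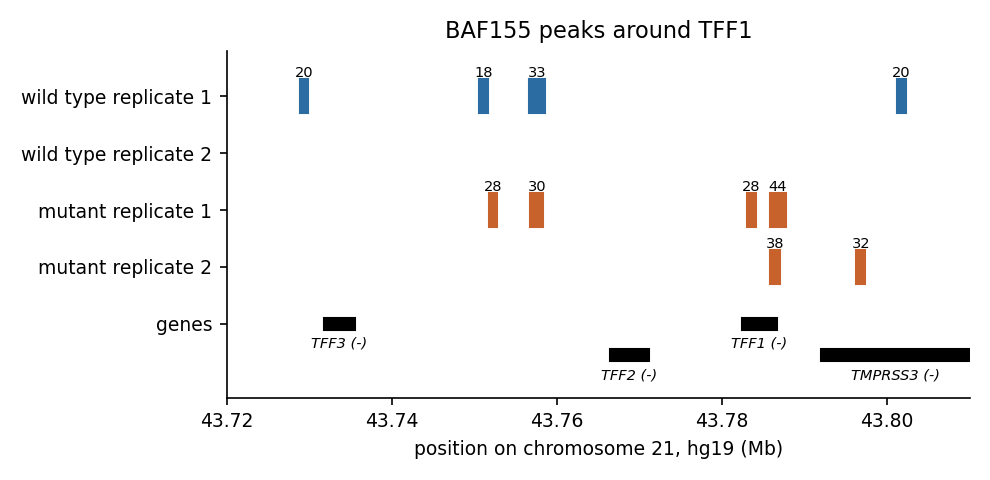
Map of chromosome 21 around TFF1, with position in Mb (hg19) on the horizontal axis, peaks of the 4 libraries as boxes with their normalised tags, and genes as black bars with their strand. Peaks of 44 and 38 normalised tags lie over the TFF1 start site in the mutant libraries, and no wild-type peak does.

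The strongest wild-type-only regions lay mostly in introns or far from start sites. An intron of SNX27, an endosomal sorting gene, on chromosome 1, 151593856 to 151600210, had 91 and 135 normalised tags. An intron of CHD6, a chromatin remodeller gene, on chromosome 20, 40178819 to 40183203, had 74 and 106. An intron of TRPM7, an ion channel gene, on chromosome 15, 50923744 to 50929140, had 91 and 62. Of the 10 strongest, those at AKAP9 (71 and 55 normalised tags) and at CENPO and PTRHD1 (70 and 59) lay at promoters, and introns of NAALADL2 and TANC2 and stretches beyond KCNJ3, CDH12 and PRDM9 held the rest. Among the 10 strongest mutant-only regions, promoters were those of GYG1, a glycogen primer gene, on chromosome 3, 148708116 to 148709707, with 43 and 45 normalised tags, POLR1B, an RNA polymerase I subunit gene, on chromosome 2, 113298380 to 113300371, with 42 and 44, PDE8A, a phosphodiesterase gene, with 89 and 42, and RPRM, a cell cycle arrest gene, with 41 and 39. The others lay in introns of ADAMTSL3 (61 and 46) and VKORC1L1 and away from the genes FAM27E3, EIF3H, ATP1A1 and ZFAT. The regions nearest to SNX27, NAALADL2, CHD6, TANC2, GYG1 and ATP1A1 lay on chromosomes 1, 3, 17 or 20. Tags were concentrated there, as given below, and the ranking used tags not divided by input.

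The number of such regions depended on list length. The 4 lists merged into 16313 regions, of which 11093 (68.0%) were called in 1 library and 1036 (6.35%) in all 4. Parting the libraries by genotype gave 753 and 177 regions, 930 together. Parting them by replicate number gave 1263 and 96, 1359 together, and the crossed parting gave 321 and 242, 563 together. With lists shortened to equal length the order turned, with totals of 510 by genotype, 485 by replicate number and 379 crossed, and with 303 wild-type-only and 207 mutant-only regions. Absence from a list is no absence of BAF155, and at the common limit on tag density only 9 wild-type-only and 29 mutant-only regions were left.

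**Figure D4:**
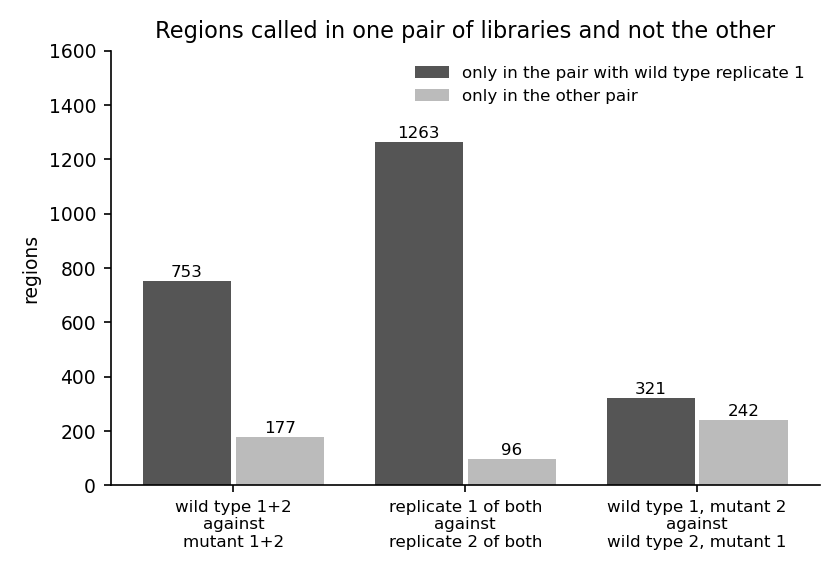
Number of regions (vertical axis) called in both libraries of a pair and in neither library of the other pair, for the 3 ways of parting the 4 libraries. Genotype gives 753 and 177 regions, replicate number 1263 and 96, and the crossed parting 321 and 242.

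Promoters took a larger part of the mutant peaks. Within 1 kb of a start site lay 14.5% (exact 95% interval 13.8 to 15.1) and 14.1% (13.2 to 15.1) of the wild-type peaks, and 16.3% (15.5 to 17.2) and 20.6% (19.3 to 22.0) of the mutant peaks. Of the mutant-only regions, 50 of 177 (28.2%, 21.7 to 35.5) lay at promoters, those of TFF1, GYG1, POLR1B, PDE8A and RPRM among them. Of the wild-type-only regions, 116 of 753 (15.4%, 12.9 to 18.2) did so, those of DDX18, PRMT2, BUB1 and AKAP9 among them, and of the shared regions 169 of 1035 (16.3%, 14.1 to 18.7). Random placement within 500 kb gave 2.79%, 2.84%, 2.99% and 3.22% for the libraries, so all 4 lists favoured promoters by 4.95-fold to 6.41-fold, each with p of 0.001. Introns held 46.0%, 45.1%, 44% and 39.2% of the peaks. Intervals cover counting error only.

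The odds ratio for promoters, mutant-only against wild-type-only regions, was 2.17 (1.48 to 3.17), with a two-sided Fisher's exact p of 0.000122 and an adjusted p of 0.000304 over 5 comparisons. Mutant-only against shared regions gave 2.02 (1.41 to 2.92, adjusted p 0.000488), and shared against wild-type-only regions gave 1.07 (0.828 to 1.38, adjusted p 0.647). All peaks gave 1.16 (1.06 to 1.26) for the replicate 1 libraries and 1.59 (1.42 to 1.77) for the replicate 2 libraries, higher in the mutant library in both. Within bins of GC content these odds ratios turned to 0.766 (0.691 to 0.848) and 0.880 (0.766 to 1.01), and with lists of equal length they were 1.04 (0.913 to 1.19) and 1.98 (1.74 to 2.26). These tests compare regions of these libraries, not replicates; the means per library, 14.3% ± 0.259 and 18.5% ± 3.04 (SD, n = 2 each), gave an exact permutation p of 0.33. Without replicate 2 the odds ratio between genotypes was 1.22, and without replicate 1 it was 2.12. GC content was 39.3%, 40.5%, 41.6% and 44.5% in the 4 lists. It was higher in the mutant lists and, within each genotype, in the library with fewer non-duplicate tags. In wild-type-only regions it was 39.4% and in mutant-only regions 46.9%. Within bins of GC content the odds ratio between these classes turned to 0.588 (0.359 to 0.962, Mantel-Haenszel p 0.0367).

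**Figure D5:**
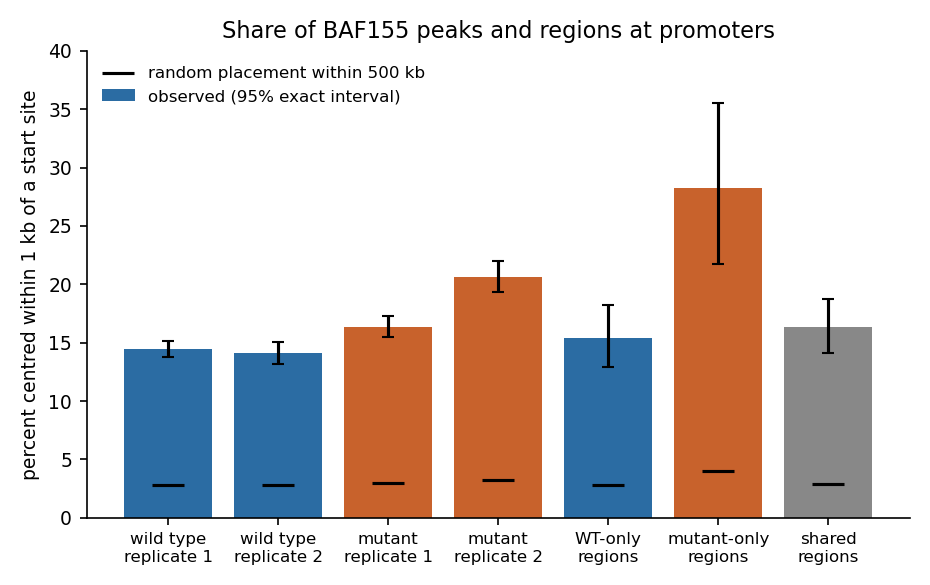
Percent of BAF155 peaks or regions centred within 1 kb of a start site (vertical axis), for each library and region class; bars are observed shares with exact 95% intervals, and black lines the mean of random placements within 500 kb. Mutant-only regions stand at 28.2% and wild-type-only regions at 15.4%, and every bar lies above its black line.

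No gene list passed the test between genes near wild-type-only and near mutant-only regions. MYC and its targets had 4 genes near wild-type-only regions, DDX18, GADD45A and HSPD1 (a mitochondrial chaperone gene) among them, and 0 near mutant-only regions. Luminal identity genes had 7 and 0, with RUNX1 and ESRP1, an epithelial splicing regulator gene, on the wild-type side. HSPD1, RUNX1 and ESRP1 also had another peak within 50 kb in 1 mutant library each, while DDX18 and GADD45A had none. Oestrogen-responsive genes had 5 and 2, with TFF1 on the mutant side. Over 748 and 249 genes, 0 of 10 lists passed the two-sided Fisher's exact test after adjustment, and 0 had an unadjusted p under 0.05. For luminal genes, with the constant added to each count, the odds ratio was 5.05 with an interval of 0.287 to 88.7. The size of a difference was thus poorly fixed at these counts. Luminal genes were more frequent near shared regions than near other regions, with 11 of 21 (odds ratio 8.83, 3.81 to 20.4, adjusted p 3.81e-05), FOXA1, GRHL2, TFAP2C, CDH1 and MLPH among them. Near wild-type-only regions their adjusted p was 0.0648.

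Motifs of AP-1 and CTCF, a chromatin loop factor, were more frequent in BAF155 peaks than in sequence 10 kb away in all 4 libraries. So were the forkhead, MYC E-box, TEAD and GRHL motifs. Odds ratios were 1.93, 1.86, 1.71 and 1.40 for forkhead, 1.18, 1.47, 1.41 and 1.68 for the MYC E-box, and 1.37, 1.52, 1.40 and 1.55 for TEAD. AP-1 matches lay in 28.7%, 29.6%, 28.8% and 30.6% of the peaks, against 18.8%, 17.1%, 18.1% and 17.5% of the flanks. CTCF matches lay in 2.65%, 3.14%, 3.13% and 2.59%, with odds ratios of 6.56 to 6.89. The GRHL motif had odds ratios of 2.75, 7.78, 4.35 and 5.05, and the oestrogen response element 2.12, 3.00, 3.40 and 2.39, the last with an adjusted p of 0.0680. Shared regions held 6 of 7 motifs more often than their flanks by the two-sided Fisher's exact test, AP-1 in 61.9% against 38.4% (odds ratio 2.60, 2.17 to 3.12) and TEAD in 43.9% against 30.1%. The oestrogen response element was the exception (adjusted p 0.148). These were 1035 regions and 952 flanks, so some regions had no flank, and the widths of the 2 sets as a whole were not compared. Against flanks matched for GC content 5 of 7 passed, as forkhead fell out (odds ratio 1.81, then 1.18 with an adjusted p of 0.603). In the central 200 bp, AP-1 (odds ratios 1.67 to 2.09), CTCF (6.95 to 9.35) and forkhead passed in all 4 libraries. TEAD passed in none of them there (odds ratios 1.15, 1.11, 1.03 and 1.09). The MYC E-box passed only in mutant 1 (0.988, 1.03, 1.40 and 0.801). GRHL passed in all but wild type 1, and the oestrogen response element only in wild type 2. In the central 200 bp of the shared regions 0 of 7 passed, with 1, TEAD, at an unadjusted p under 0.05. Matches were rarer there, but some odds ratios also fell. AP-1 went from 2.60 to 1.15 (0.720 to 1.82), the MYC E-box from 1.87 to 0.873 (0.466 to 1.63) and forkhead from 1.81 to 1.13. Over the whole regions forkhead matches lay in 96.6% of the regions and 94.0% of the flanks, so few were without a match. Whether rarer matches alone account for these falls was not tested. TEAD stood at 2.13 (1.19 to 3.83), against 1.81 over the whole regions. CTCF had matches in 0.386% of the regions and 0% of the flanks.

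Forkhead and MYC E-box motifs differed between wild-type-only and mutant-only regions. Forkhead matches, the motif of FOXA1, lay in 96.8% of the 753 wild-type-only and 91.0% of the 177 mutant-only regions (odds ratio 3.04, 1.59 to 5.81, adjusted p 0.00533). E-box matches, the motif of MYC, lay in 12.1% and 22.6% (odds ratio 0.469, 0.310 to 0.709, adjusted p 0.00477). AP-1 did not pass, at 32.1% and 33.3% (adjusted p 0.789), nor did the oestrogen response element, at 0.133% and 1.69% (adjusted p 0.0545). Both differences went with the GC content of these classes: 0 of 7 motifs passed within bins of GC content, with 1, the oestrogen response element, at an unadjusted p under 0.05. The E-box odds ratio was 0.544 (0.178 to 1.66) in the central 200 bp, where matches were fewer, and 0.620 (0.363 to 1.06) away from promoters, where regions were fewer. Its lost calls thus do not show that the difference went away. In the central 200 bp 0 passed, with 1, forkhead, at an unadjusted p under 0.05, and away from promoters only forkhead passed. Without replicate 2 the number was 6, and without replicate 1 it was 3.

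BAF155 tags were concentrated on chromosomes 1, 3, 17 and 20, in stretches of up to 635 kb. These chromosomes make up 19.5% of the genome and held 24.5%, 32.4%, 29.3% and 37.3% of the peaks and 56.9%, 67.2%, 65.8% and 72.1% of the tags in peaks. By number of peaks the excess was neither even over these chromosomes nor confined to them. Chromosome 1, 7.88% of the genome, held 7.78%, 10.0%, 9.49% and 11.6% of the peaks. Chromosome 14, outside the set and 3.09% of the genome, held 7.29%, 6.74%, 6.36% and 6.40%. Chromosome 20, 2.08% of the genome, held 20.1%, 26.4%, 25.4% and 31.2% of the tags in peaks. A stretch of chromosome 20, 52221389 to 52856802, ran over ZNF217, BCAS1 and CYP24A1 with 41630, 15276, 41141 and 19021 normalised tags; ZNF217 and BCAS1 are known from breast cancer amplification. Another, 45796078 to 46387198, ran over EYA2, ZMYND8, SULF2 and NCOA3, an oestrogen receptor coactivator gene, with 18828, 19275, 31612 and 14852. On chromosome 17, 59287168 to 59741955, BCAS3, TBX2, TBX4 and NACA2 lay under 29491, 19897, 29994 and 19974 normalised tags, and next to it, 59755129 to 59989069, BRIP1 and INTS2 lay under 20892, 21444, 19943 and 18615. The 10 strongest shared regions also covered BCAS4, PARD6B and RIPOR3, DOK5, TRIM33, and TRIM37, PPM1E and SKA2, and 2 intergenic stretches on chromosomes 1 and 6. The share of peaks on these chromosomes was 28.5% ± 5.57 in wild type and 33.3% ± 5.70 in mutant (SD, n = 2 each, exact permutation p 0.667), a difference smaller than the SD of either group. Wild type minus mutant was -4.73 percentage points for the replicate 1 libraries and -4.92 for the replicate 2 libraries.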

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

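The common limit on tag density, unstitched peaks, peaks per 1000000 non-duplicate tags, GC bins, the restriction to regions away from promoters and the comparison of lists with all genes were chosen after the data had been seen. Of the other settings fixed beforehand, 43 kept direction and call or stayed close, and 19 moved. Of those chosen later, 9 kept direction and call or stayed close, 4 moved, 3 reversed and 1 lost its call. Some of these calls could not change, so the counts do not measure robustness. Results judged by the exact permutation test, with p of 0.33 or more, could only change sign. Merging peaks within 1000 bp left the ratio of peak numbers at 1.57, as peaks were called with a minimum distance of 2500 bp. The common limit, which keeps more of the shallow lists by construction, gave a ratio of peak numbers of 0.729. It left 9 wild-type-only and 29 mutant-only regions, with a ratio of 0.310. Promoters were 1 of the 29 and 0 of the 9. The promoter odds ratio of 1 there came from the constant added to each count, so it shows neither a difference nor the lack of one. Within bins of GC content the promoter odds ratio was 0.588 and 0 motifs differed between genotypes; the cause was not tested. A reciprocal overlap of 50% gave 280 mutant-only regions and a ratio of wild-type-only to mutant-only regions of 2.68. Centres within 500 bp gave 321 and 2.42. Both settings counted peaks of 1 library of each pair in place of merged regions. Stricter matching can raise or lower such counts: wild-type-only peaks numbered 749 and 777, against 753 regions. Equal list lengths gave 303 wild-type-only regions and a ratio of 1.46, against 4.25 with the full lists. Equal lengths were not run for peak numbers, which they fix. Regions in either replicate of one genotype numbered 8487 and 3536, a ratio of 2.40. With each replicate number left out, each genotype had 1 library and no replicate to meet: wild-type-only regions ranged from 3342 to 7372, mutant-only from 1757 to 2940, their ratio from 1.90 to 2.51, and motifs that differed from 3 to 6. In the central 200 bp 0 motifs differed, and 0 were more frequent in shared regions than in flanks. Matches are fewer there by construction, but in the shared regions the odds ratio of AP-1 also fell to 1.15, while that of TEAD was 2.13. Away from promoters 1 motif differed. The cause was not tested. Counts of libraries with a peak near a named gene moved in 15 cases and stayed in 5 at the common limit, in 4 and 16 with equal list lengths, and in 3 and 17 at 10 kb.

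Whether the replicate numbers pair the libraries stays open: the labels do not say so, and the pairing check, the correlation of replicate 1 minus replicate 2 calls between genotypes over 16313 regions, was -0.0678, a value that unequal list lengths can push below 0. The mean Jaccard index was 0.407 within replicate numbers and 0.360 between them. With the replicate number as a block, the ratio of wild-type-only to mutant-only calls was 2.28, the ratio of peak numbers 1.53, the promoter odds ratio 1.53, 0 lists and 3 motifs differed, and no call was lost.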

Other observations

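The tests of stretches over 50 kb and of list length in the replicate 2 libraries alone, the redrawing of lists at their own depth and the promoter fold on the other chromosomes were chosen only after the result had been seen.

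Away from chromosomes 1, 3, 17 and 20, the 5 strongest shared BAF155 regions were intergenic stretches, most of them near centromeres, such as chromosome 6, 58773163 to 58779848, with 3901, 3989, 4484 and 4511 normalised tags in wild type 1, wild type 2, mutant 1 and mutant 2, and chromosome 19, 27731778 to 27740866, with 2190, 2182, 2370 and 2621. Stretches near centromeres were not left out, and signal was not divided by input, so whether these hold BAF155 was not tested. The examples that follow were picked after their values were seen and stand lower in the ranking. On chromosome 8, stretches of 129136244 to 129173653, 129177577 to 129216236 and 129216352 to 129245196 lay 386253, 427586 and 466361 bp from the closest MYC start site. The second had 752, 427, 430 and 471 normalised tags. SEMA3C, a secreted guidance factor gene, held an intronic region on chromosome 7, 80534972 to 80558776, with 668, 475, 534 and 356. NCAM2, a neural adhesion gene, held an intronic region on chromosome 21, 22770462 to 22801846, with 882, 254, 810 and 216. An intergenic stretch 12145 bp from GRHL2 had 412, 458, 655 and 401.

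More peaks were called in the wild-type than in the mutant libraries, with ratios of 1.63 and 1.44. Wild-type lists thinned to the depth and tag threshold of the mutant library kept at most 0.708 times the mutant library's peaks, but the same lists redrawn at their own depth already fell to at most 1.07 times, since redrawing only loses peaks, so this test decides nothing on depth. At a common limit on tag density the ratio was 0.729, and 0.628 in the replicate 1 libraries, but that limit kept 1.32% to 47.3% of the peaks and favours shallow libraries, so it decides neither for depth nor against genotype. Depth and genotype both stay open and cannot be told apart with 2 libraries each.

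Promoters such as those of TFF1, GYG1 and POLR1B took a larger share of the mutant peaks. With lists of equal length the odds ratio was 1.98 (1.74 to 2.26) in the replicate 2 libraries and 1.04 in the replicate 1 libraries. Keeping the peaks with the most tags lowered the promoter share of every shortened list, from 14.1% to 11.6% in wild type 2. Mutant 2 was not shortened and stayed at 20.6%. The cut itself thus raised the odds ratio in the replicate 2 libraries, so list length stays open in both. GC content of the recovered fragments may account for the share, since within GC bins the odds ratios were 0.766 and 0.880. Genotype also stays open, although the lower limit within bins was 0.691: mutant peaks away from promoters were richer in GC too, at 39.7% and 41.9% against 37.5% and 38.9%, so the bins could remove a genotype difference as well as a technical one. Input libraries of the same cells would test it.

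Tags in peaks were concentrated on chromosomes 1, 3, 17 and 20, over ZNF217, NCOA3, BCAS3 and BRIP1 among others. DNA copy number as the whole source stays open: peaks on these chromosomes lay at promoters 3.67-fold to 4.90-fold more often than after random placement within 500 kb, but extra copies lift promoter peaks too, and the fold on the other chromosomes was 5.57 to 7.34. For the stretches over 50 kb copy number may be the source: at least 96.0% of them lay on these chromosomes in every library, and at least 87.6% of their bases were covered by each other library. They held 33.2%, 33.7%, 41.0% and 35.2% of the tags in peaks. No biological explanation was tested, as the stretches were called in both genotypes.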
